A study of Mus musculus with 22 samples.

How the data were processed

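The series holds 22 RNA-seq libraries from C57BL/6J mice. Bone marrow mesenchymal stem cells (MSC) had been expanded from sorted cells of wild type (WT) mice or of mice lacking Lama4 (KO). They were sequenced after culture alone or after being sorted out of a 48 h co-culture with MLL-AF9 acute myeloid leukaemia (AML) cells, and the AML cells of the same kind of co-culture were sequenced too. Per the labels' protocols, sorting used CD45, CD44 and SCA1 for MSC and CD45.1 for AML cells, cDNA was made with SMART-Seq v4, libraries with Nextera XT, and reads were single-end and 75 bp long. The protocols name 2 kinds of sequencer without saying which library ran on which, so a sequencer batch could not be tested.

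The authors deposited raw counts per gene for each library. Per the file headers these are counts of reads aligned with STAR and assigned with featureCounts. Per the submitters' processing notes STAR was version 2.6.1d, featureCounts came from Subread, reads were checked with FastQC 0.11.8 and MultiQC 1.7, and the genome was GRCm38/mm10. The file header writes the name of a human build beside the mouse species name. The strand setting and the annotation version are not given in the sources used here, so overlapping and antisense genes could not be told apart. The same table holds the authors' log2 fold changes for 4 comparisons, which per the file headers come from DESeq2's Wald test with a beta prior, and the authors' adjusted p-values from that fit. The mean count per gene was the same in all 4 comparisons, as in a single fit over the series.

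Columns were mapped to samples by their names, which match the sample titles, and groups follow the titles. The table has 27179 gene rows, of which 1275 carry no symbol. Those rows took 0.501% to 0.825% of the counts of a library. They were kept in the tests and library sizes and left out only of the genes named. Coordinates come from the RefSeq annotation of GRCm38.p6, where 93.0% of the rows matched by identifier. Replicates of a group were compared by a chi-square test of their counts, and the smallest statistic was 4.3 per degree of freedom, so no pair within a group looked like 1 library deposited under 2 names. Pairs from different groups were not tested this way. The labels do not say whether replicates were separate animals or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

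Each comparison was fitted with edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM normalization, the filterByExpr filter and the robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Only the libraries of the 2 groups compared entered a fit, except that the interaction of genotype and co-culture used all 16 MSC libraries. Levels are TMM-normalized CPM (counts scaled to a common library size), given as mean ± SD. Ratios of summed counts carry exact 95% intervals, and a group without counts was set to a floor of 3 counts over the group. Intervals and floors cover counting error only, since reads were amplified by PCR without molecular identifiers. Library depth ran from 11201751 to 24826876 counts.

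Gene lists written before the data were examined were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, 33 lists in MSC and 25 in AML cells, with adjustment over the lists of a comparison. Each was tested again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. The genes named were chosen by a rule set before the data were examined. It takes Lama4 in every comparison, and the 10 largest increases and 10 largest decreases among genes past the threshold with an average log2 CPM of at least 3, no overlap between the libraries of the groups and an approved-looking symbol. It also takes up to 2 members that rose and 2 that fell per list, by smallest adjusted p, or the 2 with the smallest p where none passed. The text gives part of the genes the rule takes, in its order, and says where a gene was chosen after its values were seen. A result withheld for evaluation is not reported here.

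The fits were tested on simulated data drawn at the real means and library sizes, with 200 genes changed 2-fold or 4-fold and a list of 20 more changed 2-fold. Each gene was drawn on its own, without correlation between genes and without a library that stands apart. The shares below therefore need not hold for the real libraries. Of genes changed 2-fold, 41.5% were recovered for KO_MSC against WT_MSC (13200 genes), 67.5% for WT_MSC_AML against WT_MSC (13298 genes) and 51.7% for KO_MSC_AML against KO_MSC (13283 genes). The share was 64.1% for KO_MSC_AML against WT_MSC_AML (13561 genes), 38.5% for the interaction (14040 genes) and 76.9% for KO_AML against WT_AML (12306 genes). Of genes changed 4-fold, the recovered shares in the same order were 83.8%, 91.8%, 79.0%, 80.8%, 60.6% and 94.0%. Unchanged genes made up 3 of 135 calls, 8 of 176, 9 of 149, 13 of 168, 5 of 110 and 21 of 205 in the same order, so the false share lay above the 0.05 aimed at in KO_MSC_AML against KO_MSC, in KO_MSC_AML against WT_MSC_AML and most in the AML comparison. DESeq2's Wald test called 41, 49, 46, 43, 31 and 22 unchanged genes in the same simulated data and order. Its larger counts below may therefore hold more false calls.

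Alternatives set before the data were examined were DESeq2 1.42.0 (size factors in edgeR, and its Wald test), no filter and a stricter filter on low counts, the replicate number as a block, a 2-fold minimum, all MSC libraries in a joint fit, only genes lower in the other cell type, and each library left out in turn. Restricting libraries by Xist and Ddx3y, a covariate of log2 Xist and a count over autosomal genes were added after seeing the data.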

Results

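The transcriptomes of bone marrow MSC, stromal cells that support haematopoiesis, and of MLL-AF9 AML cells were measured to ask how loss of Lama4, which encodes the laminin α4 chain, changes the stroma and its exchange with leukaemia cells. MLL-AF9 AML cells are a mouse leukaemia driven by a fusion of the MLL and AF9 genes. The libraries form 6 groups: WT_MSC (n = 4), KO_MSC (n = 4), WT_MSC_AML (MSC sorted from co-culture, n = 5), KO_MSC_AML (n = 3), WT_AML (AML cells sorted from co-culture with WT MSC, n = 3) and KO_AML (AML cells sorted from co-culture with KO MSC, n = 3). Total counts per library ran from 16202792 to 24826876 in WT_MSC, 15595872 to 18930208 in KO_MSC and 17961146 to 22204798 in WT_MSC_AML. They ran from 14455817 to 16207629 in KO_MSC_AML, 13997061 to 21507251 in WT_AML and 11201751 to 17359002 in KO_AML.

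Lama4 (Entrez gene 16775; GRCm38 chromosome 10, 38965515 to 39110188) followed the genotype labels in every library. It stood at 309 ± 11.0 CPM (SD, n = 4) in WT_MSC and 0.554 ± 0.278 CPM (n = 4) in KO_MSC, a ratio of summed counts of 576 (95% interval 419 to 814; 25018 against 38 counts). In co-cultured MSC it stood at 234 ± 37.3 CPM (n = 5) in WT_MSC_AML, with 4 counts over the 3 KO_MSC_AML libraries (ratio 2770, interval 1082 to 10167). KO_MSC_AML replicate 3 carries an AML cell type label, while its title, description and genotype say MSC. Its Ptprc, which encodes CD45, was 0.47 CPM, against at least 217.62 CPM in the 6 AML libraries. Its Col1a1, a type I collagen chain, was 16151 CPM, against at most 144.99 CPM there, and it was analysed as MSC.

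**Figure D1:**
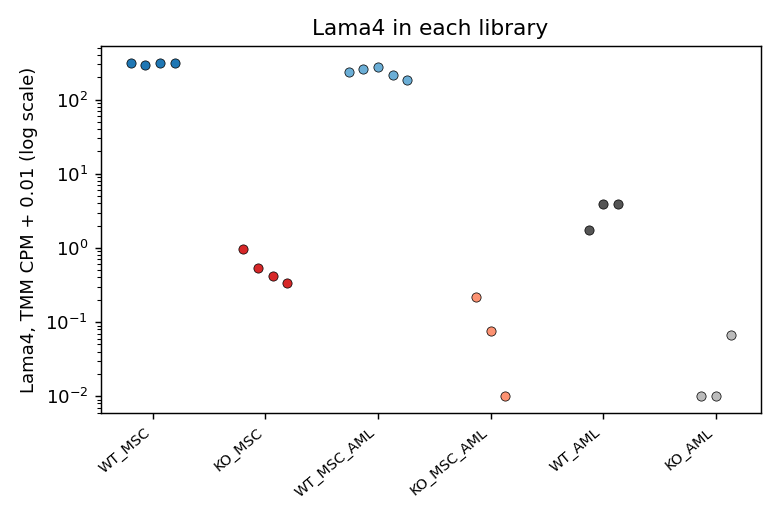
Lama4 level of each library by group (horizontal axis), as TMM-normalized CPM plus 0.01 on a log axis; each point is 1 library. WT_MSC libraries lie between 292.97 and 315.77 CPM and KO_MSC libraries between 0.33 and 0.95 CPM.

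The MSC libraries differed within groups in sex-linked transcripts and in overall profile. Xist, expressed from the inactive X chromosome, was at 212.33 CPM in WT_MSC replicate 1 and at most 0.49 CPM in replicates 2 to 4, where the Y-linked Ddx3y was at 50.06 CPM or more. In KO_MSC, replicate 3 had Xist without Ddx3y, replicates 2 and 4 the reverse, and replicate 1 had both (Xist 165.58 CPM, Ddx3y 37.77 CPM). All 5 WT_MSC_AML libraries had Ddx3y and little Xist (up to 6.82 CPM), and all 3 KO_MSC_AML libraries had Xist (337.78 CPM or more) and little Ddx3y. WT_MSC replicate 1 was nearest to KO_MSC replicate 2 (Spearman's rho 0.977 across genes, which are not independent replicates), whereas WT_MSC replicate 2 was nearest to WT_MSC replicate 3 (0.996).

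**Figure D2:**
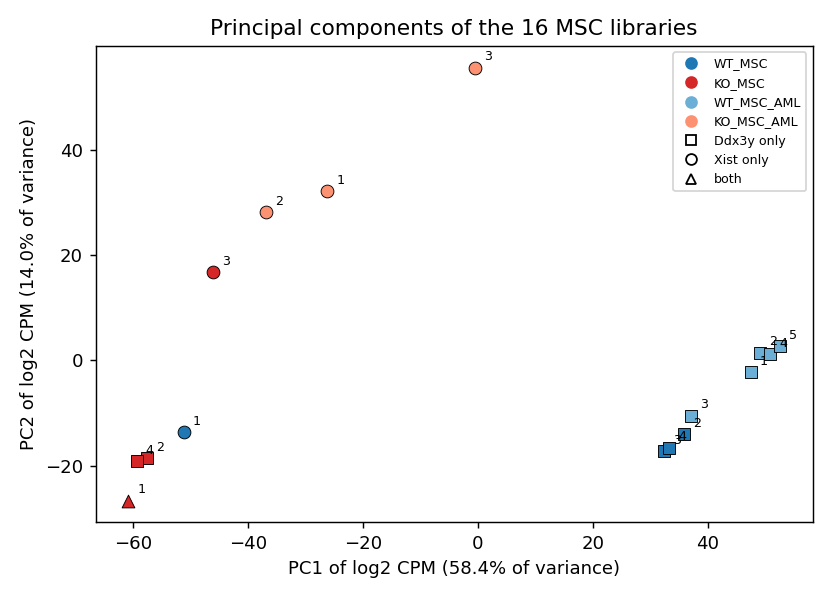
Principal components 1 and 2 of log2 CPM in the 16 MSC libraries (58.4% and 14.0% of the variance); colours give the group, symbols whether Xist, Ddx3y or both were present, and numbers the replicate. WT_MSC replicate 1 lies at −51.2 on the first component, among the KO_MSC libraries (−46.18 to −60.89), while the other WT libraries lie at 32.42 or above.

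KO MSC cultured alone expressed cell cycle genes at lower levels than WT MSC, and Scara5, Dio3 and Cfb were among the largest increases. Scara5, a ferritin receptor, stood at 1089 ± 354 CPM (n = 4) in KO_MSC and 112 ± 77.8 CPM (n = 4) in WT_MSC (log2 fold change 3.29, SE 0.48, edgeR adjusted p = 0.0140). Dio3, a deiodinase that inactivates thyroid hormone, stood at 696 ± 339 against 66.3 ± 26.5 CPM (3.39, SE 0.43, adjusted p = 0.00931), and Cfb, complement factor B, at 289 ± 230 against 21.1 ± 11.3 CPM (3.77, SE 0.78, adjusted p = 0.0301). Slfn5 (log2 4.55), Apod (4.11) and Adh1, an alcohol dehydrogenase (3.62), also rose. Among the largest decreases after Lama4 (−9.11, SE 0.29, adjusted p = 6.86e-06) were Gatm, which catalyses the first step of creatine synthesis (−4.56), and the homeobox genes Hoxb9 (2.62 ± 0.682 against 47.7 ± 9.44 CPM; −4.18, SE 0.25, adjusted p = 0.000591) and Hoxc8 (−3.34). The proliferation marker Mki67 fell from 76.4 ± 46.0 CPM in WT_MSC to 5.53 ± 2.34 CPM in KO_MSC (−3.79, SE 0.72, adjusted p = 0.0266), and the replication helicase gene Mcm5 from 32.9 ± 20.3 to 2.95 ± 0.695 CPM (−3.47, SE 0.67, adjusted p = 0.0276). WT_MSC replicate 1 had Mki67 at 9.33 CPM, near the KO_MSC libraries, while the other WT_MSC libraries had at least 83.7 CPM.

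Of the 36 cell cycle genes tested, 26 fell and 0 rose in KO_MSC (30 fell and 1 rose when adjusted over the list alone), with a median log2 fold change of −2.52. The mitotic kinase gene Bub1 (−4.13) and the spindle gene Tpx2 (−2.82) had the smallest adjusted p. Of 18 genes of the unfolded protein response 5 fell (8 adjusted over the list alone), among them Manf (−0.69) and Hyou1 (−0.55), and of 12 smooth muscle and contractile genes 2 fell, Smtn (−0.87) and Cnn1 (−1.44; 4 fell adjusted over the list alone). Of 16 factors of the haematopoietic stem cell niche 3 rose (4 adjusted over the list alone), including Kitl, the ligand of KIT (1.30), and the Notch ligand Jag1 (1.34). Of 20 basement membrane genes 5 rose, such as Nid2, a nidogen (0.91), and the collagen gene Col18a1 (2.35; 5 rose and 1 fell adjusted over the list alone). In the type I interferon list 1 of 18 genes rose, Xaf1 (0.80; 7 adjusted over the list alone), and in the list of p53 targets and senescence 1 of 18, Bbc3 (0.70; 0 adjusted over the list alone). Ribosomal protein genes had a median of −0.59 with 0 of 40 past the test, and oxidative phosphorylation genes a median of −0.25 with 2 of 37 lower, Ndufb8 (−0.59) and Ndufv2 (−0.38). These 9 lists passed camera with the preset correlation (adjusted p from 2.14e-16 for cell cycle to 0.0408 for basement membrane). None of the 33 lists passed with an estimated correlation, where cell cycle, niche factors, interferon response and unfolded protein response had adjusted p = 0.488 with an estimated correlation and the other 5 adjusted p = 0.725 with an estimated correlation.

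In all, 1545 of 13344 genes passed in KO_MSC against WT_MSC, 699 higher and 846 lower. DESeq2 called 3209, and the authors' deposited table holds 4142 calls, which include 1493 of the 1545, all in the same direction. The count rested on single libraries: it was 6242 without WT_MSC replicate 1, 55, 84 and 63 without WT_MSC replicates 2, 3 and 4, and 824, 122, 756 and 106 without KO_MSC replicates 1, 2, 3 and 4. With only the 5 libraries that had Ddx3y and lacked Xist, a choice made after seeing the data, it was 8178 of 13622, and 1538 of the 1545 genes were among them. These libraries are part of the same comparison, so the overlap is no independent support.

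**Figure D3:**
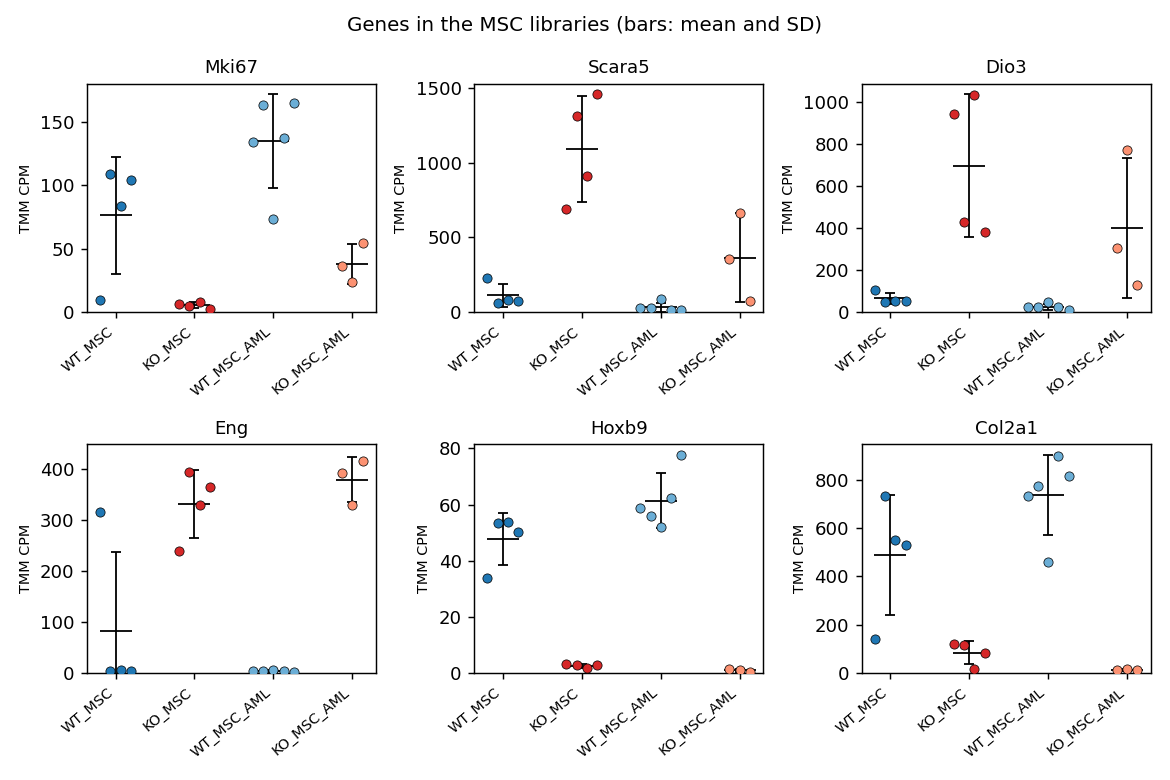
TMM-normalized CPM of 6 genes in the 4 MSC groups (horizontal axis); points are libraries and bars give mean and SD, drawn from 0 upward. Mki67, Hoxb9 and Col2a1 are lower and Scara5, Dio3 and Eng higher in most KO libraries, and WT_MSC replicate 1 lies at 316.5 CPM for Eng, near the KO libraries.

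WT MSC sorted from co-culture contained transcripts of neutrophil granules and of blood cells in general that WT MSC alone nearly lacked. Mpo, myeloperoxidase, stood at 62.8 ± 34.4 CPM (n = 5) in WT_MSC_AML and 0.659 ± 0.634 CPM (n = 4) in WT_MSC (log2 fold change 6.49, SE 0.71, edgeR adjusted p = 0.00788), and Elane, neutrophil elastase, at 17.8 ± 8.62 against 0.114 ± 0.0979 CPM (7.12, SE 0.57, adjusted p = 0.00261). Ctsg, cathepsin G (6.75), the proteoglycan gene Srgn (4.28) and Ucp2, a mitochondrial carrier (2.34), rose too. Prg4, lubricin, fell from 1241 ± 408 to 425 ± 154 CPM (−1.56, SE 0.27, adjusted p = 0.0324) and S100a4, a calcium-binding protein gene, from 861 ± 117 to 495 ± 71.5 CPM (−0.81, SE 0.13, adjusted p = 0.0247). WT_MSC replicate 1 had Prg4 at 1847 CPM, against 955 to 1093 CPM in the other WT_MSC libraries. Lars2 (−1.59) and the oxytocin receptor gene Oxtr (−1.33) fell, as did the histone genes H2bc4 (−1.22) and H2ac18 (−1.20), whose values are uncertain because near-identical copies share reads. None of the decreases named here passed without WT_MSC replicate 2, 3 or 4, or without WT_MSC_AML replicate 2 or 4. Lama4 differed by −0.41 (SE 0.12), which did not pass (adjusted p = 0.162).

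Of 17 pan-haematopoietic genes 13 rose in WT_MSC_AML (15 adjusted over the list alone), among them Coro1a (4.81), and of 15 myeloid granule and differentiation genes 7 rose (10 higher and 2 lower adjusted over the list alone). In the MLL-AF9 programme 2 of 20 genes rose, Lmo2 (5.95) and Myb (5.54; 2 adjusted over the list alone). These lists had adjusted p = 7.85e-50, 1.31e-20 and 0.00475 with the preset correlation. They had adjusted p = 0.0635 with an estimated correlation for the first pair and adjusted p = 0.326 with an estimated correlation for the MLL-AF9 programme. Cell cycle (median 0.49), cholesterol synthesis (0.25) and mitochondrially encoded genes (0.51) were higher as lists, and Wnt pathway (−1.29), antioxidant and NRF2 target (−0.32), p53 target and senescence (−0.35) and inflammatory cytokine genes (−0.45) lower, with 0 members past the test over all genes. Adjusted over the list alone, 8 of 11 Wnt genes were lower, 1 of 22 antioxidant genes was higher and 3 lower, and 1 of 18 inflammatory genes was lower. WT_MSC replicate 1 stood apart in genes of the cell cycle, Wnt and p53 lists, shown here by 1 gene of each. Against the other WT_MSC libraries its Aspm was 3.13 CPM (20.3 to 24.9), its Dkk2 112 CPM (8.20 to 9.19) and its Cdkn1a 1194 CPM (327 to 367). Its share of mitochondrially encoded counts did not stand apart, at 1.725% against 1.651% to 1.86%. Of these 7 lists none held, with adjusted p = 0.407 with an estimated correlation for Wnt, 0.613 for mitochondrially encoded genes, 0.570 for p53 targets and 0.501 for the rest. Mitochondrially encoded genes took 5.126% of counts in WT_MSC_AML replicate 5 and 1.467% to 2.362% in the other WT_MSC_AML libraries.

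In all, 100 of 13439 genes passed in WT_MSC_AML against WT_MSC, 86 higher and 14 lower. The balance of directions differed by tool: DESeq2 called 300 higher and 244 lower, and the authors' deposited table holds 681 higher and 764 lower. All 86 higher genes were also higher in the AML libraries than in MSC alone, and 13 of the 14 lower genes were lower there. With adjustment over only the 6060 genes lower in AML than in MSC alone edgeR called 0, with 1248 at an unadjusted p under 0.05. A set of 92 genes at 100 CPM or more in AML and under 1 CPM in every library of MSC alone was present in the co-cultured MSC libraries at a median of 0.377% to 2.38% of its AML level. The count was 207 without WT_MSC replicate 1, 26, 26 and 37 without WT_MSC replicates 2, 3 and 4, and 40, 60, 255 and 30 without WT_MSC_AML replicates 1, 2, 3 and 4.

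**Figure D4:**
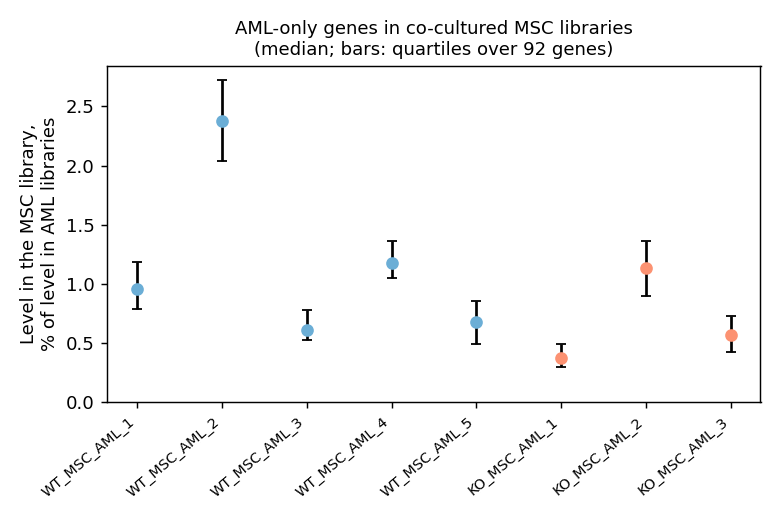
Level of 92 AML-only genes in each co-cultured MSC library (horizontal axis) as a percentage of their mean level in the 6 AML libraries; points are medians over the genes and bars quartiles. The median ranges from 0.377% in KO_MSC_AML replicate 1 to 2.38% in WT_MSC_AML replicate 2.

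KO MSC sorted from co-culture contained more transcripts of proliferation genes and of blood cells than KO MSC alone. Mki67 stood at 38.2 ± 15.8 CPM (n = 3) in KO_MSC_AML and 5.53 ± 2.34 CPM (n = 4) in KO_MSC (log2 fold change 2.78, SE 0.40, edgeR adjusted p = 0.0409), and Mcm5 at 15.9 ± 1.85 against 2.95 ± 0.695 CPM (2.42, SE 0.21, adjusted p = 0.0314). The cyclin gene Ccna2 (2.85) and the topoisomerase gene Top2a (2.11) rose as well, and Mpo stood at 49.8 ± 44.9 against 0.251 ± 0.310 CPM (7.53, SE 0.91, adjusted p = 0.0340). The level of these genes in AML cells times the AML share of each library came to 14.0% of the increase of Mki67, 31.3% of that of Mcm5 and 93.9% of that of Mpo. The ribosomal RNA gene Rn45s fell from 4817 ± 804 to 1258 ± 352 CPM (−1.94, SE 0.26, adjusted p = 0.0340) and Rn18s by 1.98, both uncertain because these genes exist in many copies. The lower Rn45s was not particular to KO: it ran from 3055 to 4680 CPM in WT_MSC. In WT_MSC_AML it ran from 851 to 1363 CPM apart from replicate 5, at 3064 CPM. Slc22a18 (−1.35), the glutathione transferase gene Mgst1 (−1.31) and Atp9a (−1.20) fell too.

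Of the 36 cell cycle genes 10 rose in KO_MSC_AML and 0 fell (26 higher and 1 lower adjusted over the list alone), with a median of 1.62. These are set against the same 4 KO_MSC libraries in which the list was lower than in WT_MSC. Of 11 pan-haematopoietic genes 4 rose, such as Rac2 (7.92), with 9 adjusted over the list alone, and of 12 myeloid granule genes 6, such as Elane (7.40), with 7 higher and 3 lower adjusted over the list alone. Of 17 glycolysis genes 0 passed over all genes and 12 were higher adjusted over the list alone (median 0.72), and of 15 hypoxia response genes 1 rose, Egln3, a HIF prolyl hydroxylase (1.48; 5 adjusted over the list alone). Ribosomal protein (median 0.42) and unfolded protein response genes (0.23) were higher as lists. Mitochondrially encoded (−0.37, with ND3 lower by −0.76), Wnt pathway (−1.13), immediate early and heat shock (−0.35), p53 target (−0.26) and antigen presentation genes (−0.18) were lower as lists. All 12 passed with the preset correlation, from adjusted p = 3.3e-27 for cell cycle to 0.0498 for antigen presentation. None of the 33 held, with adjusted p = 0.473 with an estimated correlation for cell cycle and pan-haematopoietic genes and from 0.628 to 0.736 for the other 10.

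In all, 100 of 13452 genes passed in KO_MSC_AML against KO_MSC, 76 higher and 24 lower. DESeq2 called 899 higher and 882 lower, and the authors' deposited table holds 1391 higher and 874 lower. Of the higher genes, 66 of 76 were also higher in AML than in MSC alone, and of the lower genes 18 of 24 were lower there. With adjustment over only the 6197 genes lower in AML than in MSC alone edgeR called 0, with 1679 at an unadjusted p under 0.05. The count was 1324 without KO_MSC replicate 3, 1, 0 and 0 without KO_MSC replicates 1, 2 and 4, and 0, 969 and 5 without KO_MSC_AML replicates 1, 2 and 3. With only the libraries that had Xist and lacked Ddx3y, chosen after seeing the data, 0 genes passed and 611 had an unadjusted p under 0.05. This leaves 1 KO_MSC library, assumed to vary like the co-cultured ones. KO_MSC replicates 1, 2 and 4 had Ddx3y and the KO_MSC_AML libraries little of it, so co-culture and sex-linked transcripts partly coincide.

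After co-culture, Eng and Bmp5 were among the genes higher in KO MSC than in WT MSC, and Col2a1 and Hoxb9 among those lower. Eng, the TGF-beta co-receptor endoglin (chromosome 2, 32646595 to 32682669), stood at 380 ± 44.2 CPM (n = 3) in KO_MSC_AML and 4.02 ± 1.37 CPM (n = 5) in WT_MSC_AML (log2 fold change 6.58, SE 0.27, edgeR adjusted p = 2.38e-07). The bone morphogenetic protein gene Bmp5 and the lectin gene Clec14a had 1162 and 1081 counts in KO_MSC_AML and 0 in WT_MSC_AML, at least 835-fold and at least 777-fold higher against a floor of 3 counts over the group. Naalad2 (10.93), Limch1 (9.27) and the growth factor gene Ereg (6.87) rose as well. Rps4l, with 1075 counts against 1 (ratio 2318, interval 415 to 91621), is uncertain because of its similarity to other copies of its ribosomal protein gene. Besides Lama4 (−11.22, SE 0.36, adjusted p = 2.42e-08), the cartilage collagen gene Col2a1 fell, at 13.4 ± 4.31 against 737 ± 165 CPM (−5.77, SE 0.31, adjusted p = 8.37e-07), with Hoxb9 at 0.954 ± 0.553 against 61.4 ± 9.86 CPM (−5.99, SE 0.31, adjusted p = 6.74e-07). Brinp3 (−6.88), the transcription factor genes Eya2 (−6.83) and Pax8 (−6.07), and Hoxc8 (−4.83) fell too. Several of these genes do not follow genotype alone: WT_MSC replicate 1, a WT library without AML cells, had Ereg at 85.1 CPM (40.2 to 57.0 in KO_MSC_AML), Eng at 316 CPM, Clec14a at 9.85 CPM and Eya2 at 12.9 CPM, at or toward the KO levels. The other WT_MSC libraries had Ereg at 0.380 to 0.669 CPM.

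Of 20 basement membrane genes 12 rose and 0 fell in KO_MSC_AML (12 adjusted over the list alone), among them Col18a1 (3.23) and the laminin α5 gene Lama5 (2.94). Of 18 p53 target and senescence genes 14 rose, such as the cell cycle inhibitor gene Cdkn2a (2.42) and Zmat3 (1.13), and 1 fell, Gdf15 (−1.61; 14 and 2 adjusted over the list alone). Both lists held, with adjusted p = 0.0303 with an estimated correlation. WT_MSC replicate 1, cultured alone, lay near the KO libraries in members of several of the lists here, with Cdkn2a at 299 CPM (66.8 to 76.0 in the other WT_MSC libraries), Lama5 at 186 CPM (24.7 to 27.9), Adamts1 at 384 CPM (151 to 164) and Adamts5 at 492 CPM (48.6 to 56.3). Of 36 cell cycle genes 30 fell, including Cenpf (−1.62) and Kif20a (−1.92), with 1 higher and 31 lower adjusted over the list alone. Of 15 niche factors 10 rose, including the adhesion molecule gene Vcam1 (3.52) and Fgf7 (1.02), with 10 higher and 1 lower adjusted over the list alone. Of 13 matrix protease genes 10 rose, including Adamts1 (1.58) and Adamts5 (2.81), and of 11 laminin receptor genes 6, including the integrin genes Itga7 (3.72) and Itgb3 (1.34), with the same counts adjusted over the list alone. Of 25 interstitial matrix genes 11 rose, such as Thbs1 (2.90), and 1 fell, Col6a2 (−0.62; 12 and 1 adjusted over the list alone). Of 12 Wnt pathway genes 4 rose, such as Dkk2 (4.15; 4 adjusted over the list alone), of 15 hypoxia genes 7, such as Adm (1.38; 8 adjusted over the list alone), and of 17 glycolysis genes 8, such as the glucose transporter gene Slc2a1 (1.32; 11 adjusted over the list alone). Of 20 cholesterol synthesis genes 9 fell, such as Nsdhl (−0.73; 11 adjusted over the list alone). These 9 passed with the preset correlation and not with an estimated one: adjusted p = 0.474 with an estimated correlation for cell cycle, 0.0671 for niche factors, 0.192 for proteases, 0.304 for laminin receptors, 0.599 for interstitial matrix, 0.401 for Wnt, 0.354 for hypoxia and 0.797 for glycolysis and cholesterol synthesis. By fry 13 lists passed, among them all of these but glycolysis and cholesterol synthesis.

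In all, 4306 of 13710 genes passed in KO_MSC_AML against WT_MSC_AML, 2314 higher and 1992 lower, and the count was 2958 to 4535 with any 1 library left out. The WT_MSC_AML libraries had Ddx3y and the KO_MSC_AML libraries Xist in every case, so sex-linked transcripts and genotype coincide. Of 12898 autosomal genes 4129 passed, and a fit of all 16 MSC libraries with log2 Xist as a covariate, added after seeing the data, called 117, of which 108 were among the 4306. The joint fit without that covariate called 3894. Because Xist and genotype coincide in co-cultured MSC, the covariate can take up genotype as well, so the drop does not separate sex from genotype.

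Whether co-culture changed KO and WT MSC differently was tested by the interaction of genotype and co-culture, and no gene passed in edgeR: 0 of 14247, with 1102 at an unadjusted p under 0.05, while DESeq2 called 30. In the simulated data of this comparison DESeq2 called 31 unchanged genes. Lama4 itself differed by −2.13 (SE 0.62, adjusted p = 0.529). With the preset correlation 16 lists passed. The co-culture difference was higher in KO than in WT for glycolysis (median difference 0.76), basement membrane (0.71), cell cycle (0.90), laminin receptors (0.66), hypoxia response (0.46) and 6 more, and lower for mitochondrially encoded genes (−0.92) and 4 more. No list held, with adjusted p from 0.293 to 0.640 with an estimated correlation over the 16. Leaving out WT_MSC replicate 1 gave 11 genes and leaving out KO_MSC replicate 3 gave 81.

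AML cells sorted from co-culture with KO MSC differed from those sorted from co-culture with WT MSC in 6 of 12444 genes. Chil3, a chitinase-like protein gene of myeloid cells, stood at 96.4 ± 5.40 CPM (n = 3) in KO_AML and 68.7 ± 8.27 CPM (n = 3) in WT_AML (log2 fold change 0.49, SE 0.09, edgeR adjusted p = 0.0392). Chil3 still passed without WT_AML replicate 1 and kept its direction but not the threshold when any other library was left out, or with adjustment over only the genes lower in MSC. Lama4 had 152 counts in WT_AML and 1 in KO_AML (ratio 135, interval 23.8 to 5352; log2 −6.73, SE 0.80, adjusted p = 0.00105). Among the genes past the threshold were also the insulin-like growth factor binding protein gene Igfbp3 (−5.31), Irx3 (−4.20) and Itih2 (−4.87), which lie below the level the naming rule asks for and were chosen after their values were seen. In KO_AML these 3 genes had at most 4 counts over the 3 libraries each. Interstitial matrix genes, markers of stroma, stood in WT_AML at a median of 1.07% and in KO_AML of 0.611% of their level in the co-cultured MSC of the same genotype.

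Of the 25 lists tested in AML cells 7 passed with the preset correlation and had 0 members past the test. Cholesterol synthesis (median −0.11), interstitial matrix (−0.45), mitochondrially encoded (−0.19), antigen presentation (−0.10), MLL-AF9 programme (−0.07) and haematopoietic stem and progenitor genes (−0.07) were lower and oxidative phosphorylation genes (0.05) higher. None held, with adjusted p = 0.262 with an estimated correlation for cholesterol synthesis and 0.823 for the rest. DESeq2 called 20 genes, and the authors' deposited table holds 41, which include 5 of the 6. In the simulated data of this comparison DESeq2 called 22 unchanged genes. The count was 10, 2 and 3 without WT_AML replicates 1, 2 and 3 and 1, 28 and 2 without KO_AML replicates 1, 2 and 3, and among the 8235 genes lower in MSC edgeR called 0, with 449 at an unadjusted p under 0.05.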

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

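Of the tests in this part, the shares of random splits and the share of AML RNA in MSC were set before their results were seen; the tests on sex, culture, genotype, the response of MSC and stromal RNA were chosen after.

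Within groups of 4 or 5 libraries, 18 of 72 pairs of group and measure had a library far from the rest; chance gives about 1 in 20. In WT_MSC, replicate 1 stood apart in the share of counts without a symbol (0.68%), the share of the top 10 genes (11.1%), Xist (212.3 CPM), Ddx3y (0.8054 CPM), Scara5 (227.6 CPM), Dio3 (105.9 CPM), Prg4 (1847 CPM) and Eng (316.5 CPM). Replicate 2 of WT_MSC stood apart in Lama4 (293.0 CPM) and Rn45s (3055 CPM). In KO_MSC, replicate 1 stood apart in genes detected (16850), replicate 3 in the share of the top 10 genes (13.71%) and replicate 4 in Mpo (0.7098 CPM). In WT_MSC_AML, replicate 5 stood apart in the share of mitochondrially encoded counts (5.126%) and Rn45s (3064 CPM), and replicate 3 in Scara5 (85.51 CPM), Cfb (13.22 CPM) and Prg4 (691.8 CPM).

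For 16 gene lists the co-culture effect passed the interaction test with the preset correlation, and for 0 with an estimated correlation or by fry. The median log2 difference was 0.7121 for basement membrane, 0.6568 for laminin receptors, 0.4722 for interstitial matrix, 0.3842 for smooth muscle, 0.4691 for TGF-beta and YAP targets, 0.2952 for matrix proteases, −0.2241 for antigen presentation, −0.9162 for mitochondrially encoded genes and 0.7613 for glycolysis. It was 0.4608 for hypoxia response, 0.9043 for cell cycle, −0.1804 for cholesterol synthesis, 0.1862 for the unfolded protein response, −0.3066 for immediate early and heat shock genes, 0.423 for ribosomal proteins and −0.2653 for the MLL-AF9 programme.

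The 1545 genes called between KO_MSC and WT_MSC were weighed first. Sex of the cultures as the whole cause was weighed with only the 5 libraries that had Ddx3y and lacked Xist. There the median signed log2 fold change of these genes was 0.904 (bootstrap interval over genes 0.853 to 0.943), not below its 0.802 in all 8. The genes and their signs were chosen from libraries that include these 5, which favours a high median, and the interval does not cover the spread between cultures. Still, 8178 of 13622 genes passed among these 5 libraries, alike in Xist and Ddx3y, which argues against sex as the whole cause in them. The size of that count may rest on spread within cultures only. Spearman's rho was 0.995 to 0.996 among WT_MSC replicates 2 to 4 and 0.996 between KO_MSC replicates 2 and 4. WT_MSC replicates 2 to 4 may come from a culture that differs from the others beyond genotype, since 78.0% of the 6242 genes called without replicate 1 have replicate 1 nearer to the KO_MSC mean. The Lama4 genotype stays open: 21.2% of the called genes separate all 9 WT from all 7 KO libraries of MSC in the same direction, and for these as for the rest genotype and culture cannot be told apart, because the labels do not say which libraries share a culture. The culture was weighed only for this comparison.

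Haematopoietic transcripts in co-cultured MSC were weighed next. They may be RNA or cells of the AML culture left in the MSC libraries: of the 92 AML-only genes, 98.9% (median over 8 libraries) lay within 3-fold of the median share of their library, although the sort for cells without CD45 would remove intact AML cells. Mpo was at 6388 CPM in AML, and its carried level came to 114% of its increase in WT_MSC_AML. A response of the MSC to co-culture stays open: of the genes called lower, 13 of 14 in WT and 18 of 24 in KO were lower in AML than in MSC alone, which AML RNA at shares up to 2.38% would not bring, but with adjustment over such genes alone edgeR called 0 in both genotypes.

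The genes that differed between the AML groups were weighed last. Stromal RNA in the AML libraries may account for the levels of the lower genes in WT_AML, where 5 of 5 lay within 3-fold of their WT_MSC_AML level times the stromal share; the sort for CD45.1 would remove intact stroma. This does not settle their levels in KO_AML. For Chil3 stromal RNA is argued against, since it would carry 0.0143% of the difference, though the call itself did not pass when any library other than WT_AML replicate 1 was left out. A response of AML cells to KO stroma in Chil3 stays open, untested.

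Other splits of the same libraries into groups of the same sizes were counted, the real one included. For KO_MSC against WT_MSC, 2 of 35 splits gave as many genes, so chance is not excluded; the highest other count was 2788 against the real 1545, from WT_MSC replicate 1 grouped with KO_MSC replicates 1, 2 and 4, which points to a structure of the samples. For WT_MSC_AML against WT_MSC, 1 of 100 drawn splits did (real 100, highest other 0), and for KO_MSC_AML against WT_MSC_AML 1 of 56 (real 4306, highest other 2). These shares speak against chance only if the libraries are independent. The labels do not say which libraries share a culture, so a chance difference between cultures is not excluded. For KO_MSC_AML against KO_MSC, 2 of 35 splits gave as many genes and chance is not excluded. KO_MSC replicates 1, 2 and 4 against the rest gave 868 against the real 100, again a structure of the samples. They are the libraries of this comparison with Ddx3y, so sex-linked transcripts and co-culture partly coincide. For the interaction all 100 drawn splits gave at least the real 0, and the highest gave 1871. For KO_AML against WT_AML the 10 splits are too few for a share under 0.05 (real 6, highest other 38).

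For the counts of gene lists past the preset correlation, 27 of 35 splits gave as many for KO_MSC against WT_MSC (real 9, highest other 19), 80 of 100 for WT_MSC_AML against WT_MSC (10 and 16), 14 of 35 for KO_MSC_AML against KO_MSC (12 and 17) and 39 of 56 for KO_MSC_AML against WT_MSC_AML (11 and 17). Chance is not excluded for these. For the interaction 3 of 100 drawn out of 3920 did (16 and 17). That share does not decide on chance, because these splits mix the genotypes within each culture state and so do not keep the genotype difference. The count at the preset correlation was 11 without WT_MSC replicate 1, and it was 0 with an estimated correlation or by fry. For the AML groups 5 of 10 did, too few splits to decide (7 and 9).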

How the results depend on the processing

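Restrictions by Xist and Ddx3y, the Xist covariate and the count over autosomal genes were chosen after seeing the data; the other alternatives were planned. The cause of a change was not tested unless named. DESeq2's Wald test called 3209 genes in KO_MSC against WT_MSC, 544 in WT_MSC_AML against WT_MSC, 1781 in KO_MSC_AML against KO_MSC, 30 in the interaction and 20 between the AML groups. A joint fit of all 16 MSC libraries called 2977, 151 and 935 in the first 3 of these and 3894 in KO_MSC_AML against WT_MSC_AML. DESeq2 size factors in edgeR gave 58 genes in KO_MSC_AML against KO_MSC, no filter on low counts 214 and a stricter filter 48, and no filter gave 49 between the AML groups. Asking for 2-fold too, which removes calls by construction, left 610 genes in KO_MSC against WT_MSC and 1550 in KO_MSC_AML against WT_MSC_AML. Adjusting over only genes lower in the other cell type gave 0 in WT_MSC_AML against WT_MSC, 0 in KO_MSC_AML against KO_MSC, 2347 in KO_MSC_AML against WT_MSC_AML and 0 between the AML groups. Libraries with Ddx3y and without Xist gave 8178 genes in KO_MSC against WT_MSC, and libraries with Xist and without Ddx3y 0 in KO_MSC_AML against KO_MSC. With log2 Xist as a covariate in that joint fit the counts were 1521 in KO_MSC against WT_MSC (820 higher, 701 lower, 1013 shared with the 1545), 200 in WT_MSC_AML against WT_MSC, 1160 in KO_MSC_AML against KO_MSC and 117 in KO_MSC_AML against WT_MSC_AML. In the last of these Xist and genotype coincide, so its count does not separate sex from genotype.

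With each library left out in turn, which also lowers the sample number, the counts of genes ran from 55 to 6242 in KO_MSC against WT_MSC, from 26 to 255 in WT_MSC_AML against WT_MSC, from 0 to 1324 in KO_MSC_AML against KO_MSC, from 0 to 81 in the interaction and from 1 to 28 between the AML groups. The counts of lists ran from 7 to 14 in KO_MSC_AML against KO_MSC and from 1 (without KO_AML replicate 1; 3 without KO_AML replicate 3) to 8 between the AML groups. With an estimated inter-gene correlation 0 lists passed in every comparison except KO_MSC_AML against WT_MSC_AML, where 2 did. By fry's directional test 4 lists passed in KO_MSC against WT_MSC, 5 in WT_MSC_AML against WT_MSC and 0 in KO_MSC_AML against KO_MSC, in the interaction and between the AML groups.

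Same-numbered libraries did not match throughout: their lowest correlation was −0.058 in KO_MSC against WT_MSC, −0.045 in WT_MSC_AML against WT_MSC, −0.057 in KO_MSC_AML against KO_MSC, −0.339 in KO_MSC_AML against WT_MSC_AML and −0.020 between the AML groups. In no comparison did every library correlate best with its own number. Replicates 1 and 3 did in KO_MSC against WT_MSC (0.201 and 0.257) and in KO_MSC_AML against KO_MSC (0.25 and 0.281). So did replicate 3 in WT_MSC_AML against WT_MSC (0.079) and replicate 1 between the AML groups (0.257). A partial pairing is therefore not excluded. With the replicate block the counts were 270, 25, 139, 1142 and 58 in the same order. In KO_MSC_AML against KO_MSC the block turned the balance to 55 higher and 84 lower, with 29 genes shared.

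Single named genes kept their direction and side of the threshold in 420 of 612 values in KO_MSC against WT_MSC, 452 of 577 in WT_MSC_AML against WT_MSC, 388 of 623 in KO_MSC_AML against KO_MSC, 690 of 739 in KO_MSC_AML against WT_MSC_AML, 763 of 773 in the interaction and 224 of 249 between the AML groups. With the Xist covariate Adcyap1r1 turned to −0.073 in KO_MSC_AML against WT_MSC_AML, and in the interaction Myh11 to −1.81 and Timp3 to −0.20. Myh11, at 3.70 in all libraries, was −0.78 there without WT_MSC replicate 1 and 4.10 without KO_MSC_AML replicate 3. At 11201751 to 24826876 counts, genes with a few counts per group, such as the lower genes of KO_AML, are limited by depth.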

Other observations

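Of the tests in this part, that on genes near Lama4 was set before its result was seen, and those on Hox genes and protocadherins were chosen after. Across all 16 MSC libraries, alone and co-cultured, 503 of 14247 genes had every WT library on one side of every KO library, 254 higher and 249 lower in KO. Random splits of 9 against 7 gave a median of 1 such gene, and 1 of 1000 gave as many (highest 635). This share speaks against chance only if the libraries are independent. The labels do not say which libraries share a culture, so it does not tell genotype from a difference between cultures. Beside Lama4 (268 ± 48.1 CPM in 9 WT, 0.356 ± 0.322 in 7 KO libraries), they include the homeobox genes Hoxb9 (55.3 ± 11.6 against 1.90 ± 1.06 CPM), Hoxb8 (9.42 against 0.318), Hoxb2 (7.21 against 0.448) and Hoxc8 (30.9 against 2.18). Hoxc12 was higher in KO (20.1 against 8.12 CPM). The protocadherin genes Pcdhb14, Pcdhga3 and Pcdhgb4 were higher in KO (13.4, 14.1 and 12.4 against 0.901, 1.53 and 2.19 CPM) and Pcdhgb7 lower (2.90 against 16.7 CPM). The imprinted genes Dio3 (570 ± 345 against 44.2 ± 28.4 CPM) and Plagl1 (20.6 ± 15.2 against 1.04 ± 1.64 CPM) were higher. These genes were chosen after their values were seen.

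A hypothesis for the Hox genes is that the WT and KO cultures may come from cells of different positional origin, since Hox genes keep a record of position along the body. Of 30 Hox genes 5 (16.7%) separated the genotypes against 3.57% of other genes (one-sided Fisher's exact p = 0.00399, adjusted over the 3 families 0.0120), and the 8 genes of the Hoxb cluster had a median log2 ratio of −2.48. The other clusters had medians of −0.0487 (Hoxa, 10 genes, 0 separating), −1.03 (Hoxc, 9 genes) and −0.835 (Hoxd, 3 genes, 0 separating), so the difference does not run through all Hox genes. The test was chosen after Hoxb9 and Hoxc8 were seen, which are among the 5. Fisher's test also takes genes as independent. The 5 are neighbours in the Hoxb cluster on chromosome 11 and the Hoxc cluster on chromosome 15, so its p is likely too small. The same limit holds for the protocadherins, which lie together on chromosome 18. Clustered protocadherins set differently in the cultures stay open: 4 of 43 separated the genotypes (one-sided Fisher's exact p = 0.0678, adjusted 0.102; odds ratio interval 0.714 to 7.70). The criterion against this idea, a p of 0.05 or more, was met, but that interval spans 1 and excludes nothing.

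Genes linked to Lama4 on chromosome 10 may have been carried along with the targeted allele. Of 73 genes within 10 Mb of Lama4, 4 (5.48%) separated the genotypes, all lower in KO, against 3.59% of other genes (one-sided Fisher's exact p = 0.268, adjusted 0.268). The criterion set beforehand took a p of 0.05 or more as evidence against linkage, and this p meets it. That criterion was wrong, as the odds ratio of 1.56 has a 95% interval of 0.411 to 4.20, which leaves room for several times more such genes than elsewhere, so the test does not decide.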
